A study of Homo sapiens with 2 samples.

How the data were processed

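Gene expression was measured in 2 lines of MCF7, an established human breast cancer cell line that depends on estrogen and carries the estrogen receptor. MCF7-I0 is the weakly invasive parental line and MCF7-I6 is a subclone obtained by passing cells through Matrigel invasion chambers for 6 rounds, per the labels. The sample labels describe several kinds of invaded subclones, by where in the chamber the cells were collected. Which of these the MCF7-I6 values stand for is not given in the sources used here. Total RNA was turned into biotin-labelled cRNA by the Affymetrix protocol, per the labels, and the probe set names are those of the HG-U133 Plus 2.0 array.

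The values are 1 linear intensity per probe set and line, as deposited by the authors. The labels state 3 replicates per line but give a single value per probe set. How the replicates were combined, and the summary algorithm, background correction and scaling, are not given in the sources used here. Over probe sets that are not array controls, the median intensity was 11.4 in MCF7-I0 and 10.8 in MCF7-I6, and the highest values were 11009 and 11379. The 2% trimmed means over all probe sets were 72.7 and 65.5, so the deposited columns did not share a trimmed mean. Whether single arrays were scaled to a shared target before being combined is not known. Intensities under 16 made up 56.9% of the MCF7-I0 values and 58.2% of the MCF7-I6 values. The number of arrays behind each value limits the precision, and no detection calls were used here.

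Of 54675 probe sets, 62 were array controls. GEO's annotation of the platform gave exactly 1 gene symbol to 41091 of the others, several to 1801 and none to 11721. Of those with 1 symbol, 41037 were matched by gene identifier to a table of human genes on the assembly GRCh38.p14, and 0 symbols changed. That table was otherwise used only for gene length and for which genes neighbour each other, and none of its coordinates are given. Only probe sets with 1 symbol were named, which gave 19775 genes.

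Intensities were turned into log2(intensity + 16), and each difference is MCF7-I6 minus MCF7-I0 on that scale. The added 16 shrinks the differences of dim genes, so all fold sizes are on this scale. Each gene was read from its brightest probe set by mean log2 value. A gene passed the floor when that probe set reached the 50th percentile of its column in at least 1 column, and 13149 genes did. With 1 deposited value per line there is no spread between replicates, so no test or p-value was computed, and genes were counted by a fixed size of 2-fold in either direction. The pooled SD of differences between probe sets of the same gene was the only internal measure of error. It holds probe set noise and no spread between cultures.

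A total of 28 gene lists were fixed before the data were examined, together with the size rule, the floor and the rule for named genes. The 9 that bear on invasion and on the identity of the line were epithelial adhesion, mesenchymal transition, matrix proteases and inhibitors, integrins and matrix receptors, basement membrane, actin motility and invadopodia, estrogen receptor targets, luminal identity, and cell cycle. The others covered signalling, stress, metabolism, interferon response and genes of cell types that an MCF7 culture should not hold. Of 1063 list entries, 959 had a named probe set and 809 passed the floor. The 104 entries without one were not analysed here. For each list with at least 5 members past the floor, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean log2 value in 20 bins. A list was said to stand apart when it lay outside the central 95% of these. This describes the 2 columns and is no test of the lines. Of 28 lists, 1.4 would lie outside by chance if list members varied as independently as randomly drawn genes.

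Named genes were chosen by 3 rules. The first took the 15 genes with the largest positive and the 15 with the largest negative difference past the floor, where all of the gene's probe sets past the floor had the same sign. The second took, for each list, up to 2 members with the largest positive and 2 with the largest negative difference. The third took 20 genes whatever their values, among them ESR1, PGR, CDH1, VIM, MMP9, PLAU, CXCR4 and MKI67. Any gene named outside these rules is said to have been chosen after its values were seen.

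The procedure was tested on simulated data built from the comparison of MCF7-I6 with MCF7-I0, with noise drawn at the robust spread of differences between the columns in bins of brightness. Among 13076 simulated genes, 200 that were brighter than the median gene were given a change, so the shares recovered hold for bright genes. Changes of 1.5 on the log2 scale were counted in 96% of cases in each direction and 4-fold changes in 100%. Among the unchanged genes, 23 passed 2-fold. Of 100 lists of 30 unchanged genes, 3 lay outside the central 95%. The noise was normal and drawn independently for each probe set, and these lists were drawn at random. Both counts therefore leave out genes that vary together, and neither is an error rate for the measured columns.

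Alternatives fixed before the data were examined were no floor, a floor at the 70th percentile, a floor at the 90th percentile of genes of other lineages, quantile normalization, centring on the median of all genes, and removal of the brightness trend by lowess with a span of 0.3. Others were the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, adding 0, 1 or 64 before log2, size rules of 1.5-fold and 3-fold, unmatched random lists, and list means. Scaling to the spiked-in controls, leaving out the interferon response list, random lists drawn only from listed genes, and random lists matched on gene length were added after the data were seen. Leaving out replicates was not possible with 1 value per line. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with figures drawn in matplotlib 3.10.9.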

Results

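Genome-wide transcript levels were compared between parental MCF7-I0 breast cancer cells, which invade Matrigel weakly, and the subclone MCF7-I6, derived by 6 rounds of invasion through Matrigel. Matrigel is a gel of basement membrane proteins. The comparison addressed which expression differences might be involved in invasion, since the submitters describe MCF7-I6 as much more invasive than its parent. Only 1 parental line and 1 subclone were compared. Differences linked to invasion therefore cannot be told apart from others between the lines, such as those of subcloning, added passages or culture. Each line had 1 deposited value per probe set, described as 3 replicates, so no value below has a replicate error and none of the differences was tested. Differences are MCF7-I6 minus MCF7-I0 in log2(intensity + 16).

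The largest differences between the lines were those of interferon-stimulated genes, which read far lower in the invasive MCF7-I6 cells under each scaling tried. Of 49 genes of the interferon response list past the floor, 45 were at least 2-fold lower in MCF7-I6 and 0 were at least 2-fold higher. The list's median difference was -2.42, against -0.13 for random lists of like brightness, and it lay below all 10000 of them. IFI27, an interferon-induced membrane protein, had an intensity of 3368 in MCF7-I0 and 23.4 in MCF7-I6, a difference of -6.42. IFIT1, which binds viral RNA, went from 2634 to 47.3 and ISG15, a ubiquitin-like modifier, from 4718 to 400.1.

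The oligoadenylate synthetases OAS1, OAS2 and OAS3, which activate an antiviral ribonuclease, differed by -4.38, -5.35 and -3.98. IFIT3 differed by -5.12, the antiviral GTPase MX1 by -4.54 and the nucleotide kinase CMPK2 by -4.55. BST2, also called tetherin, had a difference of -4.37, the helicase-like DDX60 -4.22, IFI44L -4.14 and SAMD9 -4.05. UBE2L6, the enzyme that passes ISG15 to its targets, differed by -3.84. RIGI, a cytosolic sensor of viral RNA, differed by -3.72 at its brightest probe set and by -0.30 at its least different of 3. The probe sets of OAS3 ranged from -3.98 to -1.04. The list members inside 2-fold, named after their values were seen, were B2M at -0.9998, SAMD9L at -0.65, HLA-E at -0.61 and IRF1 at -0.41. The array's 4 control probe sets for STAT1, the transcription factor of the interferon pathway, also read lower in MCF7-I6, with differences from -2.05 to -1.77. These control probe sets were singled out after their values were seen.

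**Figure D1:**
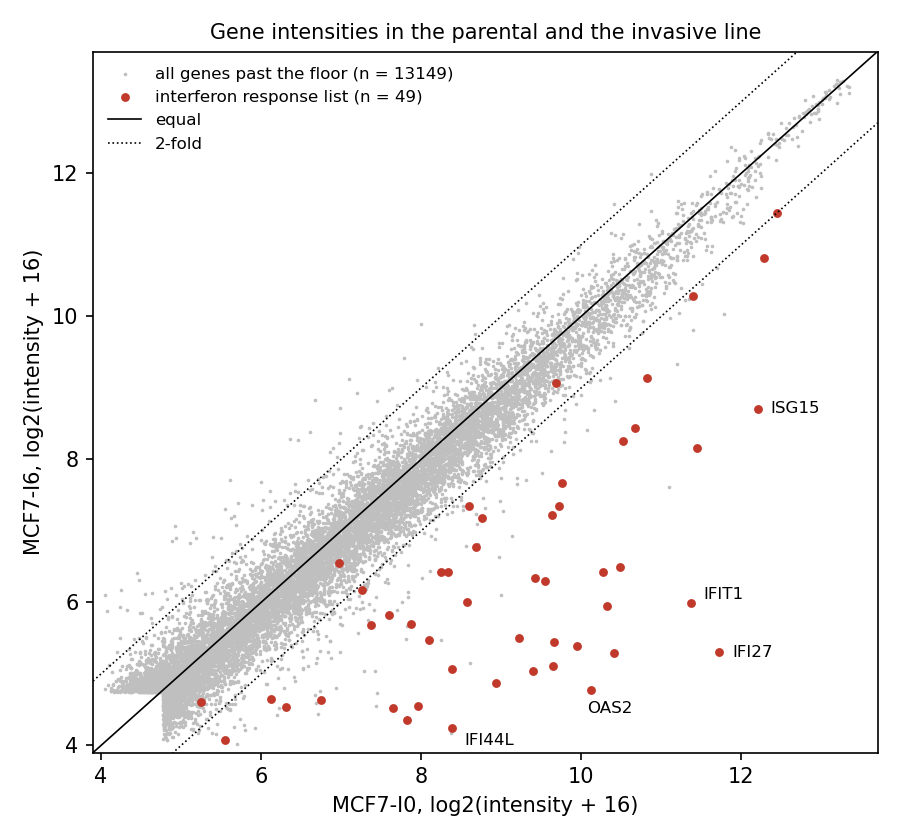
Log2(intensity + 16) of 13149 genes in MCF7-I0 (horizontal axis) and MCF7-I6 (vertical axis), each point a gene, with the 49 interferon response genes in red, the line of equality and dotted lines at 2-fold. Of the red points, 45 lie beyond the lower 2-fold line, down to IFI27 at -6.42.

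Of all 13149 genes past the floor, the interferon response genes included, 12807 (97.4%) differed by less than 2-fold. At least 2-fold higher in MCF7-I6 were 104 genes, and 238 were at least 2-fold lower, of which 193 were not on the interferon response list. Interferon response genes were 31 of the 47 genes at least 4-fold lower and 22 of the 25 at least 8-fold lower. At least 4-fold higher in MCF7-I6 were 5 genes, and 0 were 8-fold higher.

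The largest positive difference was that of NPNT, a matrix ligand of integrins, which had intensities of 86 in MCF7-I0 and 436.5 in MCF7-I6, a difference of 2.15, and its other probe set differed by 0.76. The membrane-bound serine protease TMPRSS4 went from 14.3 to 118.1 (2.15) and the prostaglandin receptor PTGER4 from 32.9 to 193.9 (2.10). AKR1C3, a steroid-metabolising reductase, differed by 2.03, the collagen gene COL3A1 by 1.96 and TGFBI, a secreted matrix protein, by 1.89, with TGFBI at 240 and 934.5. The protocadherin gene PCDH7 differed by 2.06 at its brightest probe set, from 0.5 to 52.8, and by 0.17 at its least different of 4. ARHGAP29, which switches off Rho GTPases, differed by 1.96, the neural adhesion gene CNTN3 by 1.91 and the vasodilator peptide gene ADM by 1.81. NT5E, which makes extracellular adenosine, differed by 1.79, with its 3 probe sets from 0.64 to 1.79. The others among the highest were OTULINL (1.98), EFHD1 (1.91), AHNAK2 (1.84) and SHISA2 (1.84). Of the 104 genes 2-fold higher, 21 had an MCF7-I0 intensity under the floor, so their fold depends on the value added before log2.

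**Figure D2:**
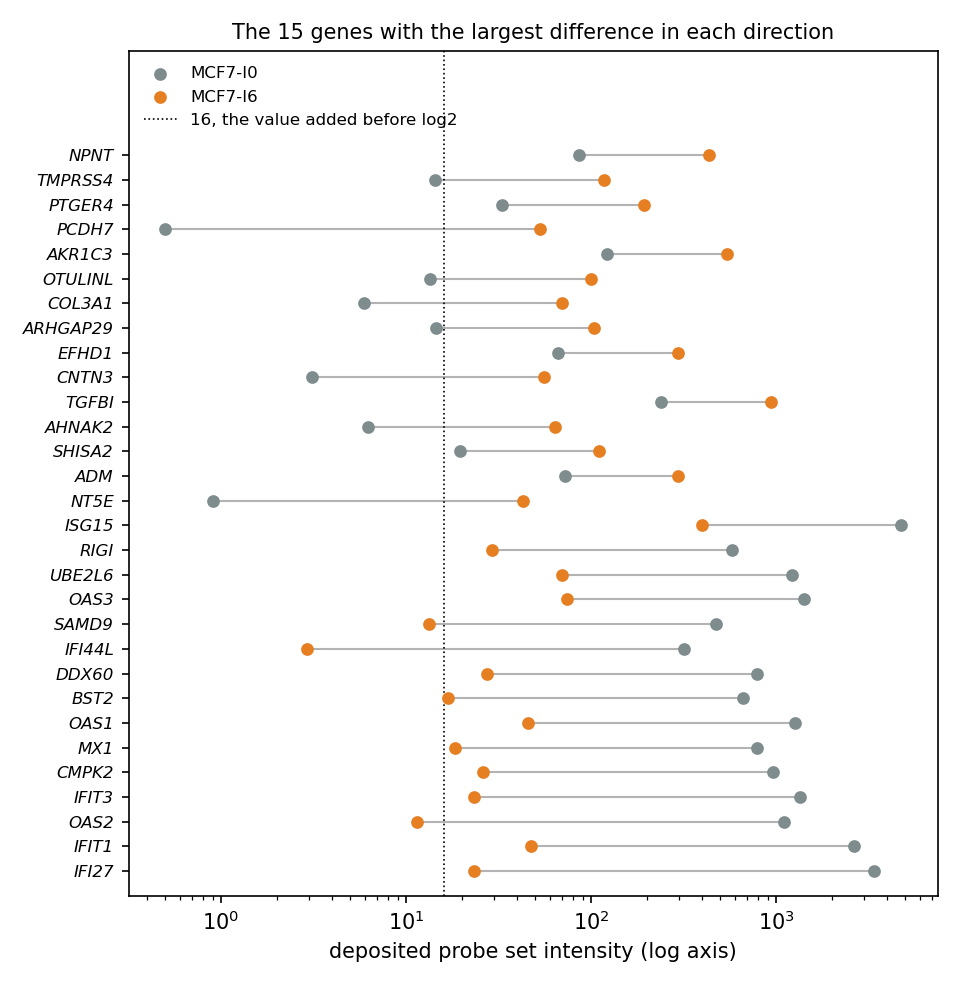
Deposited intensity (log axis) in MCF7-I0 (grey) and MCF7-I6 (orange) of the 15 genes with the largest positive and the 15 with the largest negative difference, ordered by difference on the log2(intensity + 16) scale. IFI27 at the bottom goes from 3368 to 23.4 and NPNT at the top from 86 to 436.5.

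Among the lists on invasion, basement membrane genes stood above genes of like brightness. Their median difference over 18 genes was 0.26, against -0.09 for random lists (percentile 99.98), and 1 gene was 2-fold higher and 0 were 2-fold lower. Several of the 18 were dim. LAMA4, LAMB1, LAMC3 and SMOC1, named after their values were seen, passed the floor only in MCF7-I6, which favours positive differences. SMOC2 passed it only in MCF7-I0. COL4A5, a collagen of basement membranes, differed by 1.52 and the laminin gene LAMC1 by 0.92, whereas COL4A2 differed by -0.18 and SMOC2 by -0.31. Mesenchymal transition genes had a median of 0.21 over 18 genes (percentile 99.86), with 4 at least 2-fold higher and 1 at least 2-fold lower. COL3A1 and TGFBI were the highest of these, and the smooth muscle genes TAGLN (-1.45) and ACTA2 (-0.64) the lowest. Usual markers of this transition that passed the floor differed by less than 2-fold on this scale. VIM differed by 0.28, CDH2 by 0.49, SNAI2 by 0.62 and FN1 by -0.43. CDH2 (8 and 17.8) and SNAI2 (21 and 40.7) were dim, so the added 16 shrinks their folds. SNAI1, ZEB1, ZEB2 and TWIST2, named after their values were seen, did not pass the floor. Integrins and matrix receptors had a median of 0.08 over 31 genes (percentile 99.66) and none of them was 2-fold different. PXN differed by 0.81 and SDC4 by 0.59, TNS1 by -0.75 and CD44 by -0.995, although the 9 probe sets of CD44 ranged from -0.995 to 0.03. The least different probe sets of PXN and TNS1 differed by 0.26 and -0.06. The mean of the integrins and matrix receptors was -0.01, opposite in sign to their median.

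Epithelial adhesion genes did not stand apart, with a median of -0.07 over 26 genes (percentile 80.6) and 0 genes 2-fold different. CDH1, the epithelial cadherin, differed by -0.24 at its brightest probe set and by 0.45 at another, and EPCAM by -0.14. CDH3 (0.92) and CLDN3 (0.61) had the largest positive differences, and GRHL2 (-0.60) and TJP1 (-0.49) the largest negative ones. Matrix proteases and inhibitors did not stand apart either, at -0.02 over 42 genes (percentile 87.4). Among them the protease genes TMPRSS2 (1.72) and PLAU (1.33) were at least 2-fold higher, and the inhibitor TIMP1 was 2-fold lower, from 1090 to 523.4 (-1.04). The TIMP1 call lies close to the bound and is lost after centring on the median difference of all genes (-0.11). PLAU was dim, at 6.9 and 41.7, and its receptor gene PLAUR differed by -0.58. CTSL differed by -0.81, MMP2 by -0.59, MMP14 by -0.20 and MMP9 by 0.20. Actin motility and invadopodia genes had a median of -0.05 over 48 genes (percentile 89.2). RND1 was 2-fold higher (1.10). TIAM1 was 2-fold lower at its brightest probe set (-1.09) but differed by only -0.07 at its other, and its call too is lost after centring. The probe sets of RHOC (-0.45 to 0.89) and RHOB (-0.99 to 0.43) differed in sign.

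Estrogen receptor targets had a median of -0.22 over 40 genes, at percentile 7.9 and so inside the central 95%, with 5 at least 2-fold lower and 0 higher. PDZK1 differed by -1.56 and CCN5 by -1.41, FHL2 by 0.70 and CTSD by 0.60. The progesterone receptor PGR differed by -0.21 at its brightest probe set and by -0.70 at its other. Luminal identity genes had a median of 0.03 over 29 genes (percentile 99.03), with 3 at least 2-fold lower and 0 higher. AGR3 went from 493.5 to 52.7 (-2.89) and AGR2 from 2674 to 879.5 (-1.59), while ELF5 differed by 0.96 and SCUBE2 by 0.83. ESR1 differed by -0.49, GATA3 by -0.01, KRT18 by 0.03 and CD24 by 0.22. The mean of the luminal identity list was -0.13, opposite in sign to its median, and its percentile ranged from 55.5 to 99.4 over 16 alternatives. Cell cycle genes lay in the middle, at -0.14 over 46 genes (percentile 50.8), with MKI67 at -0.06, HMMR at -1.02, CCNB1 at -0.84, UBE2C at 0.57 and TYMS at 0.46.

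Of the remaining lists, growth factor receptors and ligands (median 0.18, percentile 100), Wnt and Notch signalling (0.13, 99.96), TGF-beta and BMP signalling (0.09, 99.96), hypoxia and glycolysis (0.09, 100) and ribosomal proteins (0.03, 99.95) stood above random lists. Examples were EPHA4 (1.24) and IGFBP3 (1.16), JAG1 (1.45) and JAG2 (0.79), INHBB (1.17) and TGFB1 (1.16), and PGM1 (1.05). On the same lists, FGFR4 differed by -1.01, VEGFA by -0.54, MYC by -0.66, HEY2 by -0.66, TGFB3 by -0.92, KLF10 by -0.71 and EGLN1 by -0.67. The probe sets of VEGFA ranged from -0.54 to 0.003. Unfolded protein and amino acid stress genes (median -0.32, percentile 0.1) and oxidative phosphorylation genes (-0.26, 0.65) stood below. Scaling to the spike-ins shifts all genes alike, so it turned both medians positive and left both percentiles as they were. Of the first, PDIA4 (-1.11) and CTH (-1.04) were the lowest, and of the second ATP5MC1 (-0.90) and CYC1 (-0.85).

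Inside the central 95% were chemokines and cytokines (-0.01, percentile 82.9), sterol and lipid synthesis (-0.10, 68.5), p53 targets (-0.13, 51.1), immediate early genes (-0.06, 79.0), histone genes (-0.10, 58.8) and stem-like breast markers (0.03, 91.2). The stem-like breast markers stood above random lists with the floor at the 70th percentile (percentile 99.73), with the floor from genes of other lineages (98.5) and as a mean (99.3). The chemokines and cytokines did so without probe sets ending in _x_at or _s_at (98.5). Members of the stem-like list differed in both directions, with CD44 at -0.995, KLF4 at -0.37 and SOX2 at 0.80. Its brightest member was CD24 (0.22). The list's median takes all members alike, whatever direction each would take in stem-like cells, so it does not measure a stem-like state. Single members still differed: the chemokine receptor CXCR4 went from 110.2 to 315.7 (1.39, with 3 probe sets from 1.01 to 1.39) and its relative ACKR3 differed by 0.93. CCL5 differed by -1.40, CXCL12, the ligand of both receptors, by -0.92, and ALDH1A3 by 1.29. At their least different probe sets, CCL5 differed by -0.31 and ALDH1A3 by 0.41.

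Markers of cell types that a pure culture should not hold ranged from dim to moderately bright, and up to bright on the basal and myoepithelial list. The brightest endothelial marker in MCF7-I0, PECAM1, read 62.3. The brightest fibroblast marker, COL1A1, read 99.2 in MCF7-I0 and 105.2 in MCF7-I6, and the brightest neural and muscle marker, the myoglobin gene MB, 340.8 and 332.6, both named after their values were seen. Leukocyte lineage markers had a median of 0.12 over 9 genes (percentile 77.7), endothelial markers 0.05 over 8 (67.8), and neural and muscle markers -0.01 over 8 (65.01). CORO1A, the brightest leukocyte marker, was at 47.1 and 34.3. PECAM1 differed by -1.49, with its 4 probe sets from -1.62 to 0.01, and FGB by -1.004. Fibroblast lineage markers had a median of 0.19 over 6 genes (percentile 92.0), led by COL3A1 and FBN1 (0.85), and 10 of the 17 named members also stand on another list. The fibroblast lineage markers stood above random lists with no floor (percentile 98.6) and as a mean (99.82). Basal and myoepithelial markers stood above random lists (0.12 over 14 genes, percentile 98.93), with KRT15 at 1.68, CAV1 at 0.996 and TRIM29 at -0.59. The brightest of these, SFN, read 1396 in MCF7-I0 and 1267 in MCF7-I6, and was named after its values were seen.

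**Figure D3:**
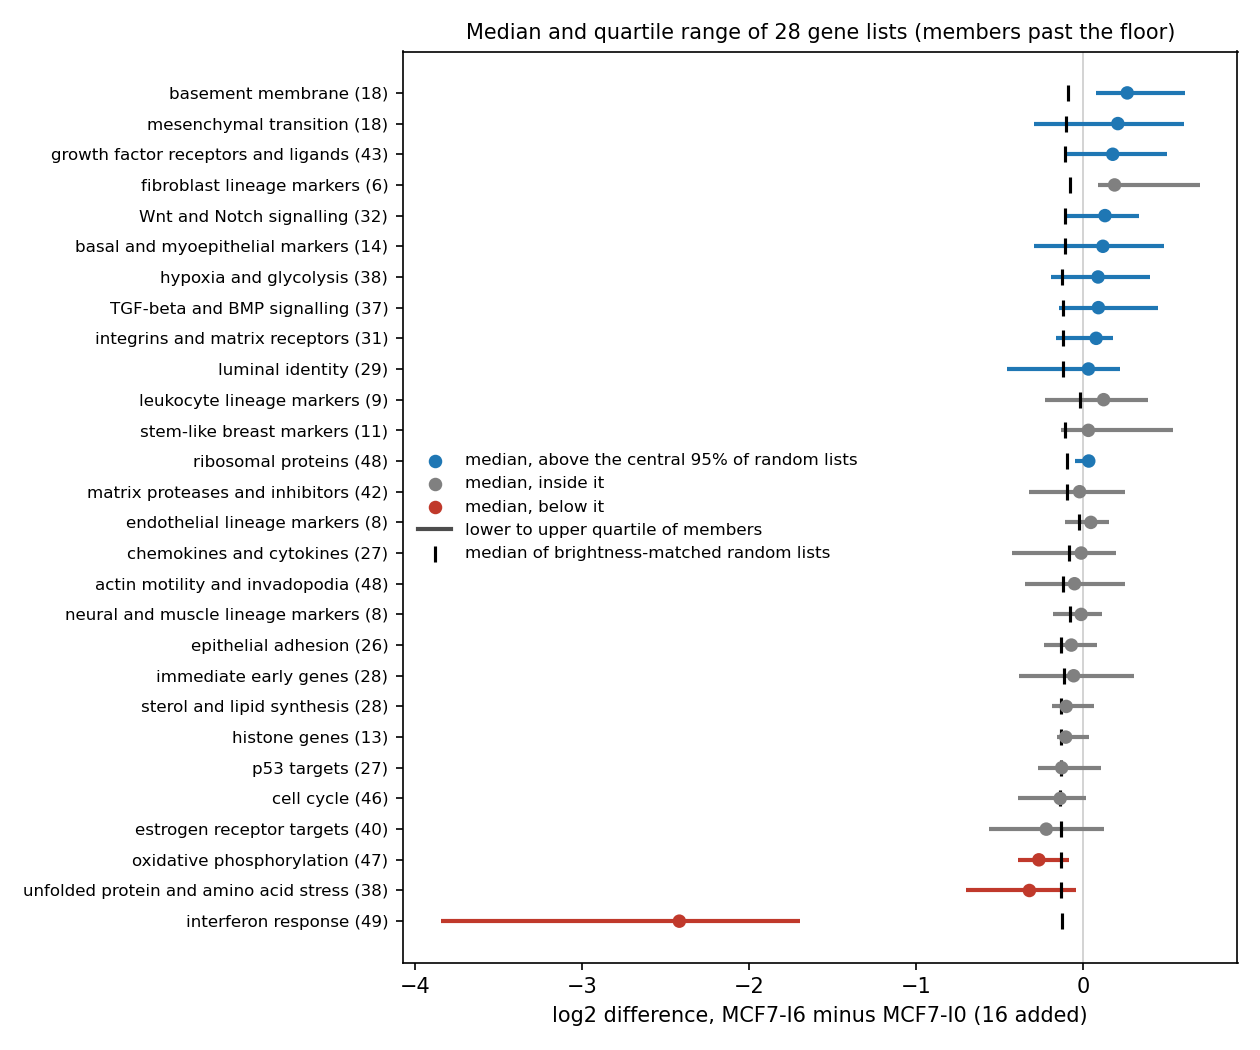
Median difference (dots, log2 scale, MCF7-I6 minus MCF7-I0) and quartile range (bars) of 28 gene lists, with the number of genes past the floor in brackets, the median of brightness-matched random lists (ticks) and the position outside or inside their central 95% by colour. The interferon response list sits at -2.42 and the other 27 medians lie between -0.32 and 0.26, of which the negative ones turned positive when all genes were shifted alike to the spike-ins.

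In all, 13 of 28 lists stood apart from random lists, 10 above and 3 below, where chance gives 1.4 for lists of randomly drawn genes. Without probe sets ending in _x_at or _s_at, the lists hypoxia and glycolysis, ribosomal proteins, luminal identity, unfolded protein and amino acid stress, and oxidative phosphorylation no longer stood apart. Against random lists of listed genes only, mesenchymal transition, integrins and matrix receptors, luminal identity, basal markers, and Wnt and Notch signalling no longer did. The median difference of all genes was -0.11, with the central 95% of genes from -0.89 to 0.67, and a list's position among random lists is set against genes sharing this shift. Of 6495 genes with several probe sets past the floor, 59.9% had the same sign in all of them, with a pooled SD of 0.25 between probe sets. Of the 176 such genes that were 2-fold different, 90.9% had the same sign, but their pooled SD between probe sets was larger, at 0.61.

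The balance of higher and lower genes depended on the scaling of the columns. The 18 hybridisation spike-in probe sets all read lower in MCF7-I6 (median -0.40), as did the 24 poly-A control probe sets (-0.45). The ratio of 3' to 5' signal was 2.05 in MCF7-I0 and 1.79 in MCF7-I6 for ACTB, and 1.08 in both for GAPDH. As deposited, 69.6% of the 2-fold genes were lower in MCF7-I6. After centring on the median of all genes, 146 genes were higher and 168 lower (53.5% lower), after quantile normalization 144 and 166 (53.5%), and with the brightness trend removed 140 and 171 (55.0%). Scaled to the spike-ins, the median of all genes moved from -0.11 to 0.29, so small negative differences turned positive, and 449 genes were higher and 108 lower (19.4%).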

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

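The results below come from probe sets that were left out of the comparison because the annotation used here gives them no gene symbol, and they were singled out after their values were seen. Of 3866 such probe sets past the floor, 38 were at least 2-fold lower in MCF7-I6 and 9 were at least 2-fold higher. The lowest were 213711_at, from 2251 to 130.5 (a log2 difference of -3.95), and 1558048_x_at (-2.48), and the highest were 203423_at (1.36) and 201540_at (1.30).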

How the results depend on the processing

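Scaling to the spiked-in controls, leaving out the interferon response list, random lists drawn only from listed genes, and random lists matched on gene length were chosen after the data were seen. The interferon response list stayed at percentile 0 in its 16 alternatives, with medians from -3.18 to -2.003. Of 440 list values under the alternatives, 411 kept their sign, where the list stood apart, and their place inside or outside the central 95%. Of 1686 values of named genes, 1308 moved by no more than 0.25, the SD between probe sets over all genes with several, and 378 moved further. Among 2-fold genes that SD was 0.61. Among the 147 named genes tried, no gene that was 2-fold different changed sign. The 15 at each end had been chosen for probe sets of the same sign, so a change of sign was unlikely for them. Genes 2-fold different that were not named were not tried. Leaving out a replicate was not possible with 1 value per line. Apart from where the change is built into the setting, the cause was not tested. Signal over background limits the folds of dim genes, and 40 of the 238 lower genes had an MCF7-I6 intensity under the floor.

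Counts of genes 2-fold higher and lower were 437 and 707 with 0 added before log2, 394 and 639 with 1 added, 28 and 105 with 64 added, and 449 and 108 when scaled to the spiked-in controls. They were 471 and 1162 at 1.5-fold and 25 and 83 at 3-fold. The actin motility and invadopodia list came to stand above random lists with no floor (-0.00116), with quantile normalization (0.10) and without probe sets ending in _x_at or _s_at (-0.00201). Luminal identity no longer stood apart with quantile normalization (0.0925), the brightness trend removed (0.0796), unmatched lists (0.0328) or lists from listed genes (0.0328). Ribosomal proteins also no longer stood apart with quantile normalization. The luminal identity value was negative with the floor at the 70th percentile (-0.00995), without _x_at and _s_at probe sets (-0.0471) and as a mean (-0.13). Without those probe sets, hypoxia and glycolysis (-0.0189) and ribosomal proteins (-0.0586) also turned negative. Scaling to the spiked-in controls shifts all genes alike and leaves percentiles as they were. It turned the negative list medians positive except that of the interferon response list, and of the lists standing apart these were unfolded protein and amino acid stress (0.0814) and oxidative phosphorylation (0.14). As means, integrins and matrix receptors turned negative (-0.0119) and estrogen receptor targets came to stand below (-0.30, percentile 2.21). Against lists from listed genes, integrins and matrix receptors (0.0787) and mesenchymal transition (0.21, percentile 97.08) no longer stood apart.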

Other observations

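The test for leukocytes, scaling to the spiked-in controls, random lists drawn from listed genes or matched on gene length, the joining of windows into stretches, and the genes and gene sets named in this part outside the fixed rules and lists, CRABP2 and DHRS3 included, were chosen after the data were seen.

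Outside the interferon response list, MUCL1, a small mucin-like protein of breast epithelium, went from 2175 in MCF7-I0 to 180 in MCF7-I6 (-3.48), and OLFML3, a secreted olfactomedin-like protein, from 209.3 to 28.9 (-2.33). MPPED2 differed by -2.88 and C9orf152 by -2.77. Several others are interferon-inducible genes that the list did not hold, such as GBP1 (-2.71), GBP3 (-2.38), PARP12 (-2.34) and SP110 (-2.20). Among the genes higher in MCF7-I6, the collagen gene COL5A1 went from 30.7 to 142.4 (1.76, with 3 probe sets from 1.59 to 1.78) and SULF1, an extracellular sulfatase, from 111.2 to 403.8 (1.72). AMIGO2 (1.64), KLK6 (1.55) and QPRT (1.78) were also higher.

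Of 13 genes that respond mainly to interferon gamma and had a named probe set, 9 passed the floor, with a median of -0.57. Only 7 of these were bright enough in MCF7-I0 to be 2-fold lower on this scale, and 0 were. Several of the 7 were dim, such as HLA-DRA (23 in MCF7-I0 and 6.3 in MCF7-I6), CD74 (18.9 and 4.8) and SOCS1 (23.9 and 23). The value added before log2 shrinks the folds of dim genes, so for these the count of 0 decides nothing. HLA-DRB1 (562.4 and 316.9) and WARS1 (785.9 and 527.6) were bright and stayed short of 2-fold. HLA-DRA differed by -0.81, HLA-DRB1 by -0.80, CD74 by -0.75, WARS1 by -0.56, SOCS1 by -0.03 and CXCL9 by 0.19. The receptor genes IFNGR1 and IFNGR2, which are not among the 13, differed by 0.04 and 0.26. This set held GBP2 (-0.54) and GBP4 (-0.57) but not GBP1, which differed by -2.71, so its median holds only for the genes chosen. The set was not compared with the interferon response list.

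For the lower interferon-stimulated genes, the scaling of the columns and a brightness trend were argued against by the list median, which was no higher than -2.01 under 4 other scalings. Centring and spike-in scaling only remove a shift of -0.11 and -0.40 from all genes alike. Neither could have brought the list median near 0, so the outcome of these was fixed beforehand. Quantile normalization and removal of the brightness trend were not bound in this way. Probes shared between related genes were argued against by a median of -3.01 without probe sets ending in _x_at or _s_at. Leukocytes in the parental culture were argued against by levels: ISG15 would need 39.2% leukocyte RNA even if it had the highest intensity on the array there, yet the brightest of 22 leukocyte markers, CORO1A, read 47.1 in MCF7-I0, under 47 of the interferon response genes. A difference between the lines themselves may account for the pattern, but how the cultures were grown and harvested side by side is not given in the sources used here, and this was not tested.

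As a hypothesis, the parental cells may have received or made more interferon, or the subclone may have responded less. Fewer receptor and kinase transcripts in MCF7-I6 were not settled: IFNAR1 had the lowest of 4 differences at -0.78, short of 2-fold, with IFNAR2 at -0.09, TYK2 at -0.12 and JAK1 at 0.29. Interferon transcripts in the parental culture were not settled either. Of 15 ligand genes with a named probe set, 2 passed the MCF7-I0 floor, and 0 of these were 2-fold lower in MCF7-I6. The brightest of them, IFNL2, read only 18.5 in MCF7-I0.

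Genes that lie near each other on a chromosome showed a weak tendency to differ in the same direction. Across 13086 genes, leaving out the interferon response list, the correlation of each gene's difference with the mean of genes 11 to 20 places away was 0.26, against -0.03 to 0.03 in 100 shuffled orders. These are genes of the same 2 columns and not independent replicates. Removing the brightness and gene length trends left it at 0.27, which argues against both, whereas base composition and shared regulation of neighbours stay open. The values are consistent with copy number differences between the lines, as a hypothesis, since the same order would also show any other effect that spans many genes.

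In windows of 50 genes, 109 of 1202 had a median below that of any window in the shuffled orders and 32 one above. Joined where they overlapped, they made 20 stretches with lower and 4 with higher medians. Among the longest, 300 genes from MROH2B to WDR55 had a median of -0.39 and 190 genes from DOCK8 to DAPK1 a median of -0.44. The 240 genes from JAG1 to SALL4 had a median of 0.22 and the 150 genes from PRPF19 to RBM4 a median of 0.17.

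Many gene lists stood above genes of like brightness, which prompted a look at whether listed genes differ as a class. The 774 listed genes had a median of -0.06, or -0.03 without the interferon response list, against -0.11 for the other genes. With random lists drawn from listed genes only, 8 of 28 lists stood apart in place of 13, so listed genes as a class may account for part of the pattern and the test did not settle it. Matching random lists on gene length as well left 13 lists apart, which argues against gene length.

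CRABP2 (1.37), DHRS3 (1.40) and ALDH1A3 (1.29, and 0.41 at its other probe set), which bind or metabolise retinoids, were among the genes higher in MCF7-I6. A wider retinoic acid response is a candidate explanation, but 8 other retinoid genes past the floor had a median of 0.09, at percentile 91.9 of matched random lists. This met the bound set beforehand for no wider response. Yet 5 of them were above 0 and 3 below, and some read near the floor, such as CYP26A1 (11.3 and 14.2) and CYP26B1 (12.1 and 6.2). A median over such members leaves the question open.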
